A study of Arabidopsis thaliana with 8 samples.

How the data were processed

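Root meristem tissue of seedlings grown for 3 days at 22 °C after 5 days of stratification was fixed and subjected to anti-GFP ChIP, per the labels' protocols. The 8 samples were 2 anti-GFP libraries and 2 input libraries from each of ARR12-GFP and Col-0. Summit lists of the 4 anti-GFP libraries were used, and the input libraries were not analysed here as separate samples. Replicate numbers came from the sample titles. The titles of the control libraries read GFP and do not name a plant line, their genotype label reads control, and the series' design text names the control genotype as Col-0. The absence of a GFP tag in the control plants rests on that design text and was not tested here.

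Per the submitters' processing notes, the tools were FastQC 0.11.2, Bowtie 1.1.1, SAMtools and MACS2 2.1.0, and the genome build was TAIR10. Settings and filters of the peak caller are not given in the sources used here. Each list that the authors deposited holds 1 summit per peak as an interval of 1 base, and the consecutive peak names in each list show that peaks were called per library. The score of each summit is the authors' own value on a −log10 scale, of a p-value or a q-value (which of them is not stated), with a lowest deposited value of 2.00. It was used only to rank or filter summits within a list. Because the number of called peaks depends on read depth and on the input, neither of which the lists give, a difference in summit number can reflect depth as well as binding.

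Genes came from a RefSeq gene table of assembly TAIR10.1, which names genes and their extent without strand, exons or sequence. All 299 identifiers of the gene lists were matched in it. The summits are in TAIR10 coordinates, so the fit of the table to them was checked from the data: in each of 20 chromosome segments the summits of ARR12-GFP replicate 1 were moved in steps of 100 bp, and the share inside protein-coding genes was lowest at a move between -200 and 100 bp. Over all segments the share was 29.2% without a move and 57.9% and 57.4% after moves of -2000 and 2000 bp. Only distances to genes are given, and no gene coordinates. Because no genome sequence was used, the planned tests of the B-type response regulator motif and of all 6-mers were not run. Promoters could not be told from 3′ regions, so the planned classes and target windows were adapted after this was known: a target gene held a site or had one within 1500 bp of either end, and sites were classed as inside a protein-coding gene, within 1000 bp of one, inside another annotated gene, or elsewhere.

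Summits on the 5 nuclear chromosomes were used. Summits of both ARR12-GFP libraries were joined by single linkage within 200 bp, a site needed a summit from each library, and its position was the midpoint of the best-scoring summit of each. Sites within 200 bp of a summit of either Col-0 library were removed. Overlaps and site numbers were compared with 1000 random circular shifts, and classes with 1000 uniform placements. The 18 gene lists were compared with all 27444 nuclear protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists, and with 10000 random lists matched on gene length. Summit numbers were compared by an exact permutation test, which cannot reach 0.05 with 2 libraries per group. Gene tests count neighbouring genes and family members as independent, and they describe the joined site list rather than the spread between plants.

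Named genes followed a rule fixed before the data were examined: 16 genes of cytokinin and root growth whether or not they had a site, up to 3 further targets per list with the highest mean score percentile, the genes nearest to the 10 highest-scoring reproducible sites, and those nearest to the 5 highest-scoring sites shared by the Col-0 libraries. Of the genes this rule names, 1 is not reported here. Alternatives were other matching distances, summits scoring at or above their list's median, other rules for Col-0 summits, other gene windows, and leaving out each library. Leaving out an ARR12-GFP library replaces the joined sites by the summits of the remaining one.

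The code was tested on simulated lists. Simulated summits were placed uniformly, and target genes were drawn independently. Real sites lie beside genes more often and neighbouring genes can share them, so these runs describe a simpler setting than the data. With 3000 shared positions in lists of the size of the ARR12-GFP ones, 3013 to 3024 sites were found in 5 runs. The list test, run 100 times with a list at 50% targets against a background of 14.0%, called a list of 26 genes in 95 runs, one of 10 genes in 39 and one of 6 genes in 13, so a short list that did not pass is not shown to lack an excess. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.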

Results

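Chromatin bound by ARR12, a B-type response regulator that acts as a transcription factor at the end of the cytokinin phosphorelay, was mapped in root apical meristems of Arabidopsis thaliana by ChIP-seq. Seedlings carried an ARR12-GFP fusion, and the same anti-GFP antibody was applied to a control genotype. The series' design text names this control as Col-0, the wild-type accession, while the sample titles call it GFP. It is called Col-0 here. Each genotype had 2 immunoprecipitated libraries from independent biological replicates. The files used here list 1 summit per called peak, and read numbers per library are unknown from them, so no value below is set against sequencing depth. Intervals are exact binomial 95% intervals and cover counting error only.

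The 1st comparison asked how the anti-GFP signal differed between ARR12-GFP and control plants. The ARR12-GFP libraries held 8137 and 5492 summits on the 5 nuclear chromosomes, and the Col-0 libraries held 199 and 251. The group means were 6814.5 ± 1870.3 (SD, n = 2) and 225 ± 36.8 (SD, n = 2), a ratio of 30.3, and the lowest ARR12-GFP library had 21.9 times the summits of the highest Col-0 library. A two-sided exact permutation test gave p = 0.333, the smallest p that the 6 labellings of 2 against 2 libraries allow. Chloroplast summits went the other way: 229 of 428 summits (53.5%) in Col-0 replicate 1 and 50 of 301 (16.6%) in Col-0 replicate 2 lay on the chloroplast genome, against 38 of 8175 (0.465%) and 0 of 5492 in the ARR12-GFP libraries. With these included the ratio was 18.7.

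**Figure D1:**
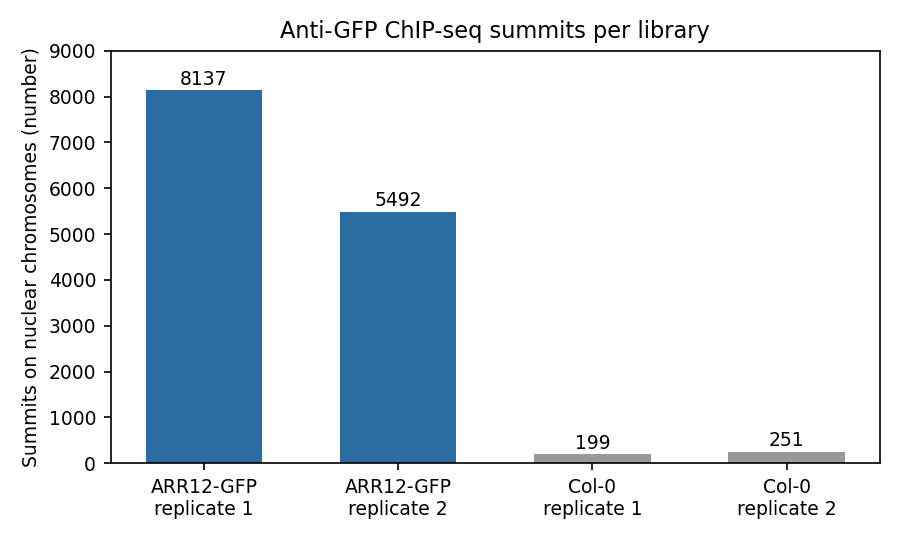
Number of summits on the nuclear chromosomes (vertical axis) in each anti-GFP library (bars, 1 library each). The ARR12-GFP libraries held 8137 and 5492 summits and the Col-0 libraries 199 and 251.

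The ARR12-GFP libraries shared many positions. Of the summits of replicate 1, 3575 of 8137 (43.9%, interval 42.9 to 45.0) had a replicate 2 summit within 200 bp, and of those of replicate 2, 3576 of 5492 (65.1%, 63.8 to 66.4) had a replicate 1 summit. Random circular shifts along the chromosomes gave means of 1.85% and 2.75% (one-sided permutation p = 0.001 for each, the smallest that 1000 shifts can give). The median distance between matched summits was 51 bp. High-scoring summits were found again more often. In replicate 1 the matched share was 16.5% in the lowest quartile of the score and 81.9% in the highest, an odds ratio of 22.9 (interval 19.4 to 27.0), with a Fisher's exact p too small for the software to represent. In replicate 2 the shares were 47.3% and 83.0%, an odds ratio of 5.45 (4.56 to 6.54; Fisher's exact test, two-sided, p = 8.66e-89).

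**Figure D2:**
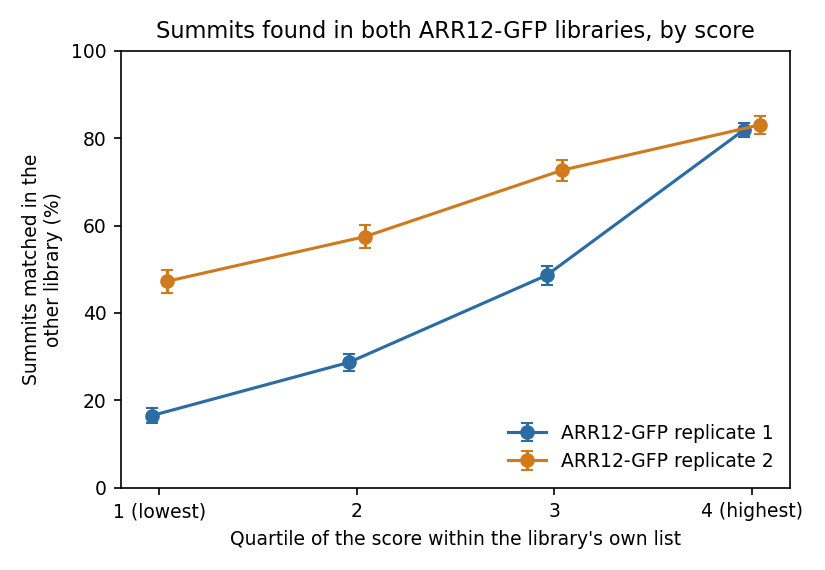
Share of summits with a summit of the other ARR12-GFP library within 200 bp (vertical axis, %) by quartile of the score within each library's own list (horizontal axis), with exact 95% binomial intervals as bars. The share was 16.5% and 47.3% in the lowest quartiles of replicates 1 and 2 and 81.9% and 83.0% in the highest.

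The Col-0 libraries coincided with each other as well. In Col-0 replicate 1, 162 of 199 summits (81.4%, interval 75.3 to 86.6) had a summit of Col-0 replicate 2 within 200 bp, against a mean of 0.0789% after shifts (one-sided permutation p = 0.001). The 5 shared Col-0 sites with the highest scores lay on chromosome 1 at 9708228, chromosome 2 at 5100001 and chromosome 3 at 14299402, 14305268 and 11895393, in TAIR10 coordinates. Their nearest protein-coding genes were AT1G27880 at 633 bp, NUB1 (AT2G12550) at 14803 bp, AT3G42075 at 65 bp, AT3G42140 at 2250 bp and AT3G30247 at 6667 bp. Each of these 5 sites also had an ARR12-GFP summit within 12 bp. Overall 95 of 199 (47.7%) and 122 of 251 (48.6%) Col-0 summits lay within 200 bp of an ARR12-GFP summit, while 1.39% of the summits of ARR12-GFP replicate 1 and 1.53% of those of replicate 2 lay that near a Col-0 summit. Without ARR12-GFP replicate 1, the share of Col-0 summits of both libraries near an ARR12-GFP summit fell from 48.2% to 30%, and with only summits scoring at or above their list's median it was 30.1%.

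Joining the ARR12-GFP summits within 200 bp gave 3574 sites with a summit from each library. Removing 71 sites (1.99%) near a Col-0 summit of either library left 3503 reproducible sites, 23.6 times the mean of 148.3 after random shifts (one-sided permutation p = 0.001). Shifts of 5 to 50 kb, which keep the regional density of each list and were chosen after the data were seen, gave a mean of 191.9. The number of sites fell to 1845 with only summits scoring at or above their list's median, and the summits of a single ARR12-GFP library outside Col-0 summits gave 8023 sites for replicate 1 and 5406 for replicate 2.

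Reproducible sites lay beside protein-coding genes more often, and inside them less often, than uniform placements. The low share inside genes held away from the gene ends. Within 200 bp inside a gene edge lay 15.3% of sites, against 9.07% of 20000 uniform placements. At 400 to 600 bp inside the edge the shares were 2.03% and 7.58%. Of the 3503 sites, 1659 (47.4%, interval 45.7 to 49.0) lay outside but within 1000 bp of a protein-coding gene, against 20.4% of uniform placements, and 1026 (29.3%, 27.8 to 30.8) lay inside such a gene, against 54.2%. The Col-0 lists were also low inside genes, with 29.6% of the nuclear summits of replicate 1 and 21.1% of those of replicate 2, so the low share was not particular to ARR12-GFP. The regions differed, however. Of the sites shared by both Col-0 libraries, 56.2% lay in the 20% of 100 kb bins poorest in genes, against 4.11% of reproducible sites. At 400 to 600 bp inside the edge the shares of Col-0 replicates 1 and 2 were 2.01% and 2.39%, near the 2.03% of reproducible sites. Shares inside genes were not compared within like regions, so a cause common to all anti-GFP lists stays open. A further 53 sites (1.51%) lay in another annotated gene only, against 8.61%, and 765 (21.8%) lay elsewhere, against 16.8%. The adjusted p of the two-sided permutation test was 0.002 for each of these 4 classes, the smallest that 1000 placements can give. The direction of the last class depended on the distance: with 2000 bp counted as beside a gene, 8.54% of sites and 10.5% of placements lay elsewhere. The 2477 sites outside genes had a median distance of 591 bp to the nearest protein-coding gene. Strand was not available in the gene table used, so 5′ and 3′ sides are not told apart, and uniform placements include repeats where reads may not map.

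**Figure D3:**
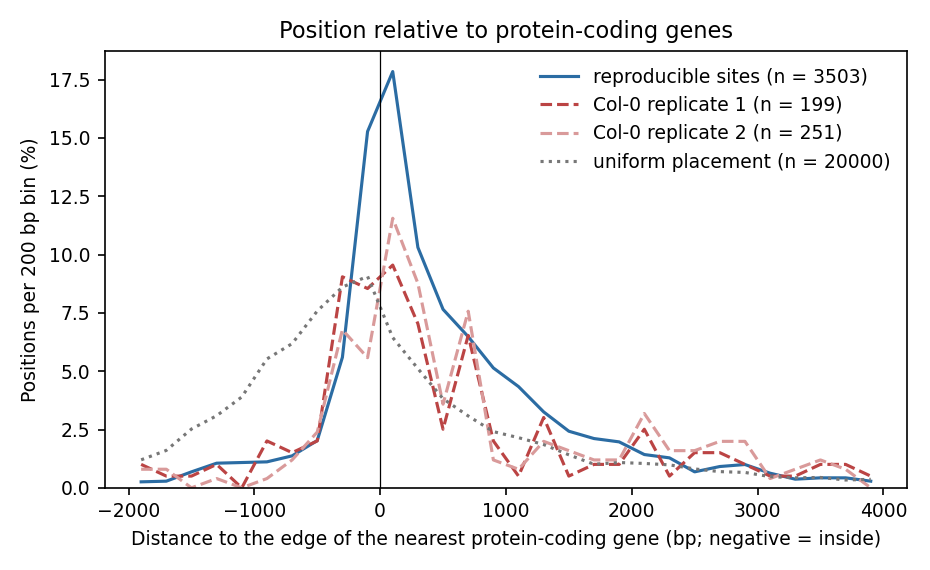
Share of positions per 200 bp bin (vertical axis, %) by distance to the edge of the nearest protein-coding gene (horizontal axis, bp, negative inside the gene), for reproducible sites (blue line), the Col-0 libraries (dashed red lines) and 20000 uniform placements (dotted line). The site curve peaks next to the gene edge, and 29.3% of sites lay inside genes against 54.2% of uniform placements.

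The next comparison asked which hormone pathways had genes near reproducible sites. In all, 3839 of 27444 nuclear protein-coding genes (14.0%) held a site or had one within 1500 bp of either end, and these are called target genes here without any statement on regulation. Of the 3503 sites, 1352 (38.6%) were assigned to more than 1 gene and 510 (14.6%) to none. The number of target genes was 2334 with 500 bp searched on either side, 2091 with only summits scoring at or above the median, and 7633 on replicate 1 alone. Of 18 gene lists fixed before the data were examined, 12 held more target genes than other genes did at an adjusted p under 0.05 in Fisher's exact test, two-sided as in every list test here, and none held fewer. They were 11 of the 15 lists of hormone, root and growth genes and the control list of broadly expressed housekeeping genes. In the latter 6 of 17 genes were targets (35.3%, interval 14.2 to 61.7; Fisher's exact test, adjusted p = 0.0380), including ACT7 (AT5G09810), ACT2 (AT3G18780) and GAPC1 (AT3G04120), so an excess over all genes was not limited to hormone genes. The housekeeping call was lost with summits matched within 100 bp, among summits scoring at or above the median and with 3000 bp searched (Fisher's exact test, adjusted p = 0.158, 0.221 and 0.187). It was kept on single libraries, with 10 of 17 genes (58.8%) near a summit of replicate 1 and 8 of 17 (47.1%) near one of replicate 2. Fisher's exact test against other genes (27.8% and 19.4%) gave adjusted p = 0.0221 and 0.0232. Against random lists matched on gene length, 3 calls did not pass after adjustment: cytokinin metabolism, expansins with proton pumps, and housekeeping genes (one-sided permutation test, adjusted p = 0.0615 for each). In the tests of single lists against matched lists, the side was that of the observed difference. Their p-values are therefore less strict than two-sided ones, as those of Fisher's exact test are. No gene of the leaf photosynthesis list was a target (0 of 20, upper limit 16.8%; Fisher's exact test, adjusted p = 0.128) and none of the seed storage list (0 of 8, upper limit 36.9%; Fisher's exact test, adjusted p = 0.687). The photosynthesis count depended on the setting, with 4 of 20 genes near a summit on replicate 1 alone, 3 on replicate 2 alone, 4 with 3000 bp searched and 2 with summits matched within 500 bp.

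**Figure D4:**
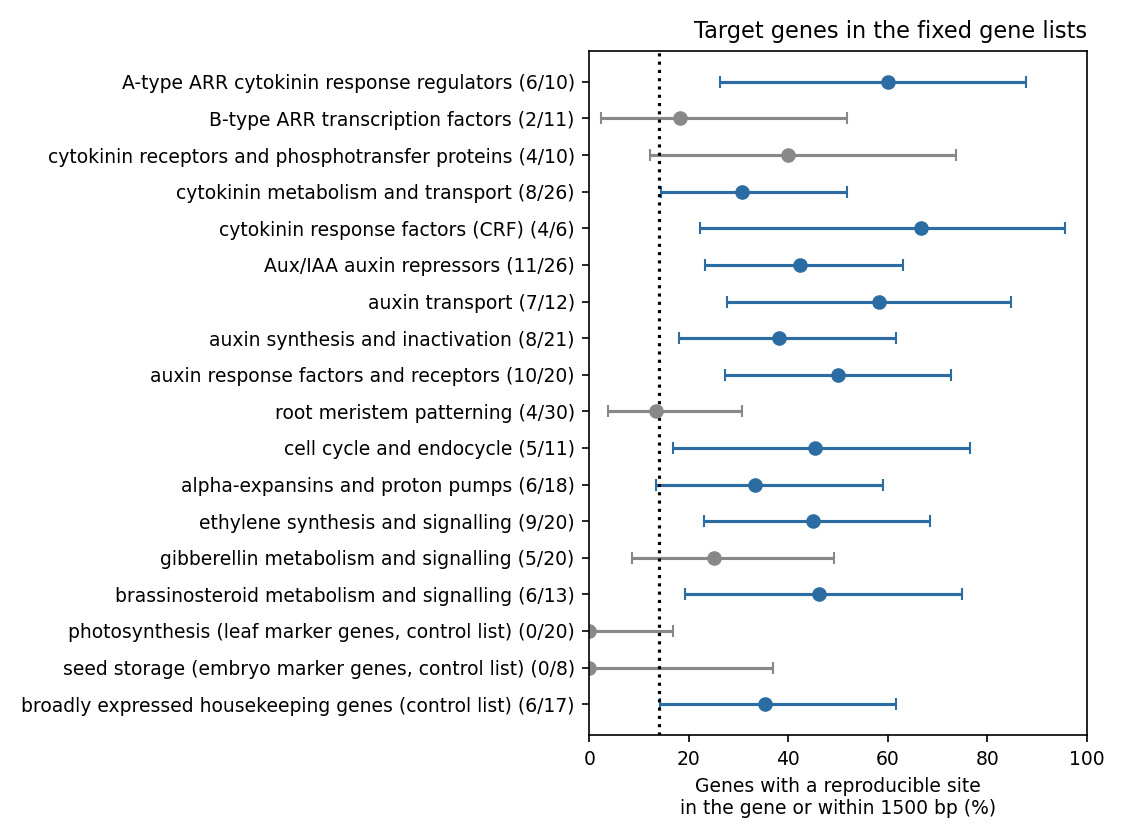
Share of the genes of each fixed list with a reproducible site in the gene or within 1500 bp (horizontal axis, %), with exact 95% binomial intervals. Blue points passed Fisher's exact test with adjustment over the 18 lists, grey points did not, and the dotted line marks 14.0%, the share of all protein-coding genes.

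Among cytokinin genes, the A-type response regulators, early cytokinin response genes whose products dampen the signal, held 6 targets of 10 (60%, interval 26.2 to 87.8; Fisher's exact test, adjusted p = 0.00340). ARR5 (AT3G48100) held a site at position 17760882 of chromosome 3 with scores of 70.5 and 33.0 in replicates 1 and 2, and ARR6 (AT5G62920) held one at 25253272 of chromosome 5 with scores of 73.4 and 24.1. ARR7 (AT1G19050) had a site 44 bp away at 6579358 of chromosome 1, with scores of 66.9 and 20.7. ARR3 (AT1G59940) had a site 901 bp away with scores of 136.7 and 52.2, and ARR4 (AT1G10470) had 3 sites in its searched region. ARR15 (AT1G74890) had no reproducible site within 11087 bp: replicate 1 held a summit of score 8.31 inside the gene, and the nearest replicate 2 summit lay 11103 bp away. In replicate 1 alone 10 of the 10 A-type genes were near a summit, and in replicate 2 alone 8 of 10.

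The cytokinin response factors held 4 targets of 6 (66.7%, interval 22.3 to 95.7; Fisher's exact test, adjusted p = 0.0122), among them CRF1 (AT4G11140) with a site inside the gene, CRF3 (AT5G53290) at 320 bp and CRF4 (AT4G27950) at 559 bp. The wider family of CRF symbols held 5 of 12 (41.7%) and did not pass over 205 families (Fisher's exact test, adjusted p = 0.263). Cytokinin metabolism and transport held 8 targets of 26 (30.8%, 14.3 to 51.8; Fisher's exact test, adjusted p = 0.0380). They included UGT85A1 (AT1G22400), with a site inside the gene scoring 115.3 and 51.1, CKX5 (AT1G75450), a cytokinin oxidase gene with 4 sites in its region, and LOG7 (AT5G06300). This call was lost on the summits of ARR12-GFP replicate 2 alone, among summits scoring at or above the median and with the nearest gene only (Fisher's exact test, adjusted p = 0.115, 0.0826 and 0.0727). It was also lost against random lists matched on the space outside genes, a setting added after the data were seen (one-sided permutation test, adjusted p = 0.0559). Cytokinin receptors and phosphotransfer proteins held 4 of 10 and did not pass (Fisher's exact test, adjusted p = 0.0551). AHK4 (AT2G01830), a cytokinin receptor, held a site with scores of 50 and 16.3, AHK3 (AT1G27320) had one at 208 bp and AHP2 (AT3G29350) at 1488 bp. The list passed on the summits of replicate 1 alone (7 of 10; Fisher's exact test, adjusted p = 0.0172) and with summits matched within 100 bp (Fisher's exact test, adjusted p = 0.0341). The B-type regulators themselves held 2 targets of 11 (Fisher's exact test, adjusted p = 0.698), ARR1 (AT3G16857) at 1150 bp and ARR20 (AT3G62670) at 949 bp. On the summits of replicate 1 alone the B-type list held 5 of 11, 45.5% against 27.8% of other genes (Fisher's exact test, adjusted p = 0.217). It lay below other genes with 18.2% on replicate 2 alone, 0% with 500 bp searched and 18.2% with 3000 bp. At ARR12 itself (AT2G25180) replicate 1 had a summit of score 9.20 inside the gene and replicate 2 had none within 12295 bp.

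Of the auxin lists, the Aux/IAA repressors held 11 targets of 26 (42.3%, interval 23.4 to 63.1; Fisher's exact test, adjusted p = 0.00259). IAA2 (AT3G23030) held a site inside the gene, IAA16 (AT3G04730) had one at 351 bp with scores of 56.3 and 25.0, and IAA17 (AT1G04250) one at 476 bp with scores of 58.3 and 23.0. IAA3 (AT1G04240, also SHY2), a repressor known to restrict meristem size downstream of cytokinin, was not a target: its nearest site, with scores of 75.9 and 22.4, lay at 1132437 of chromosome 1, 2748 bp from the gene. Auxin response factors and receptors held 10 targets of 20 (50%, 27.2 to 72.8; Fisher's exact test, adjusted p = 0.00245), among them the receptor genes TIR1 (AT3G62980) and AFB1 (AT4G03190), each with a site inside the gene, and ARF19 (AT1G19220). By symbol, the ARF family held 6 targets of 22 (27.3%) and the IAA family 9 of 24 (37.5%), in a test made after the data were seen. Neither family passed over 205 families (Fisher's exact test, adjusted p = 0.634 and 0.0745). Auxin transport held 7 targets of 12 (58.3%, 27.7 to 84.8; Fisher's exact test, adjusted p = 0.00259). The efflux carrier gene PIN2 (AT5G57090) had 2 sites, the nearer at 143 bp, and the influx carrier genes AUX1 (AT2G38120), LAX1 (AT5G01240) and LAX2 (AT2G21050) were targets. PIN3 (AT1G70940) and PIN7 (AT1G23080) had replicate 1 summits at 529 and 439 bp, while their nearest replicate 2 summits lay at 6078 and 6552 bp. With summits matched within 100 bp, 4 of the 12 transport genes were targets and the call was lost (Fisher's exact test, adjusted p = 0.0558).

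Auxin synthesis and inactivation held 8 targets of 21 (38.1%, interval 18.1 to 61.6; Fisher's exact test, adjusted p = 0.0122). GH3.17 (AT1G28130), which encodes an auxin-conjugating enzyme, had a site 157 bp away at 9825012 of chromosome 1 with scores of 60.0 and 19.2, and GH3.5 (AT4G27260), GH3.2 (AT4G37390) and YUC9 (AT1G04180) were targets as well. This call rested on the joining of both libraries: on the summits of replicate 1 alone the adjusted p of Fisher's exact test was 0.0774, and on those of replicate 2 alone it was 0.0772.

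Root meristem patterning genes did not stand apart from other genes, with 4 targets of 30 (13.3%, interval 3.76 to 30.7; Fisher's exact test, adjusted p = 1). On the summits of replicate 1 alone 13 of the 30 were near a summit, 43.3% against 27.8% of other genes (Fisher's exact test, adjusted p = 0.0858), and the list also lay above other genes with 3000 bp searched (23.3%), with the nearest gene only (16.7%) and among summits scoring at or above the median (10%), and held 1 of 30 with 500 bp searched. PLT2 (AT1G51190), a PLETHORA transcription factor gene that maintains the meristem, had a site 650 bp away at 18976526 of chromosome 1 with scores of 32.2 and 20. The others were UPB1 (AT2G47270) at 988 bp with scores of 79.2 and 44.1, TMO7 (AT1G74500) with a site inside the gene, and SCR (AT3G54220) at 749 bp. The summits inside TMO7 scored 8.16 and 4.91. The SCR site scored 14.2 and 3.37, the latter at percentile 3.58 of the replicate 2 list. PLT1 (AT3G20840) and PLT3 (AT5G10510) were not targets, with nearest sites at 34686 and 4461 bp, although replicate 1 had a summit of score 5.20 at 71 bp from PLT3. Expansins and proton pumps, which loosen and acidify the cell wall, held 6 targets of 18 (33.3%, 13.3 to 59.0; Fisher's exact test, adjusted p = 0.0463). Both pump genes, AHA1 and AHA2, were among them. By symbol, the EXPA family held 4 targets of 23 (17.4% against 14.0% of other genes), in a test made after the data were seen. Its Fisher's exact test gave an adjusted p of 0.957 over 205 families, so expansins alone showed no clear excess with 1500 bp searched. No result of the family is given here for other windows. EXPA6 (AT2G28950) held a site with scores of 71.8 and 32.7, and AHA2 (AT4G30190) held one inside the gene, where summits scored 10.5 and 4.72. EXPA4 (AT2G39700) and EXPA9 (AT5G02260) were targets, whereas the nearest site of EXPA1 (AT1G69530) lay at 1688 bp. The call of this list was lost on replicate 1 alone, without removal of Col-0 summits, among summits scoring at or above the median and with 500 bp searched (Fisher's exact test, adjusted p = 0.0835, 0.0502, 0.230 and 0.0783). It was also lost against random lists matched on the space outside genes (one-sided permutation test, adjusted p = 0.0749). In 9 of 13 alternatives of sites and windows the call was kept. With the nearest gene only and with 3000 bp searched, 9 of the 18 genes (50%) were targets (Fisher's exact test, adjusted p = 0.000288 and 0.0111).

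Cell cycle and endocycle genes held 5 targets of 11 (45.5%, interval 16.7 to 76.6; Fisher's exact test, adjusted p = 0.0237), among them CYCD3;3 (AT3G50070), RBR1 (AT3G12280) and KRP2 (AT3G50630). Ethylene synthesis and signalling held 9 of 20 (45%, 23.1 to 68.5; Fisher's exact test, adjusted p = 0.00340). EBF1 (AT2G25490), which encodes an F-box protein that targets the ethylene transcription factor EIN3, had a site 141 bp away at 10847234 of chromosome 2 with scores of 128.1 and 84.2, and ETR2 (AT3G23150) and CTR1 (AT5G03730) were targets. Brassinosteroid genes held 6 of 13 (46.2%, 19.2 to 74.9; Fisher's exact test, adjusted p = 0.0122), including the biosynthesis gene DWF4 (AT3G50660), the kinase gene BIN2 (AT4G18710) and the receptor gene BRI1 (AT4G39400). Gibberellin genes held 5 of 20 and did not pass (25%, 8.66 to 49.1; Fisher's exact test, adjusted p = 0.223), with GID1B (AT3G63010), GA3OX1 (AT1G15550) and GAI (AT1G14920) among the targets, and passed with 500 bp searched (Fisher's exact test, adjusted p = 0.0349). The cell cycle call was lost among summits scoring at or above their list's median (Fisher's exact test, adjusted p = 0.0826), and the cell cycle and brassinosteroid calls were lost with 3000 bp searched on either side (Fisher's exact test, adjusted p = 0.0821 and 0.0585). On replicate 1 alone the brassinosteroid list held 10 of 13 (76.9% against 27.8% of other genes; Fisher's exact test, adjusted p = 0.00173). On replicate 2 alone it held 6 of 13 (46.2% against 19.4%; Fisher's exact test, adjusted p = 0.0468).

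Several of the 10 reproducible sites with the highest scores lay at genes outside these lists. The highest, at 15155335 of chromosome 2 with scores of 161.7 and 92.0, lay 3226 bp from the nearest protein-coding gene, AT2G36090. EBF1 came next, followed by the sites at AT2G33180, 297 bp away, and inside AT3G10040, with scores of 131.5 and 64.1. The sites at 19451631 and 19440310 of chromosome 5 lay 3765 bp from CYP708A2 (AT5G48000) and 3561 bp from CYP705A5 (AT5G47990), neighbouring genes of thalianol metabolism. Another of the highest lay 2800 bp from BRG1 (AT5G45100). CYP708A2, CYP705A5 and BRG1 were target genes all the same, each with another reproducible site of lower score inside the gene. The remaining ones were 332 bp from LBD41 (AT3G02550), 901 bp from ARR3 and 710 bp from AT5G27730.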

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

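Shifts of 5 to 50 kb, chloroplast summits and lists matched on space were tests chosen only after the results were seen. Of 105 summary values recomputed under alternatives, 97 kept their direction and their side of the threshold, or stayed within 1.5 times for counts. Among summits scoring at or above their list's median, 1845 sites and 2091 target genes were left, fewer by construction, and with 500 bp searched on either side of genes there were 2334 targets. Leaving out 1 library at a time gave 3515 to 8023 sites and 3849 to 7633 target genes, the high values coming from ARR12-GFP replicate 1 alone, where no second library filters the summits. The ratio of summit numbers was 18.7 with chloroplast summits. Sites elsewhere were 8.54% with 2000 bp counted as beside a gene, below instead of above uniform placement. The A-type regulator, response factor, Aux/IAA, auxin response and ethylene calls were kept in 13 of 13 alternatives of sites and windows, and of 252 list values over all alternatives 224 were the same, 18 lost a call, 3 gained one and 7 changed direction. Alternatives that changed only the handling of Col-0 summits or left out a Col-0 library gave 3831 to 3910 target genes, against 3839. These hardly altered the target genes and so put the calls to little test. Lists that did not pass in the main result changed side of the background without passing: root meristem patterning was 10% among summits at or above the median score, 23.3% with 3000 bp, 16.7% with the nearest gene only, and 13.3% to 43.3% without 1 library, and the B-type regulators were 0% with 500 bp, 18.2% with 3000 bp and 18.2% to 45.5% without 1 library. The cause of these changes, and of that in sites elsewhere, was not tested.

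The labels give no shared batch or day to libraries of the same number, so these share only a number. Summits near a Col-0 summit were 0.983% of ARR12-GFP replicate 1 and 0.983% of replicate 2 for Col-0 replicate 1, and 1.2% and 1.27% for Col-0 replicate 2, which does not decide whether the numbers pair the libraries. With the replicate block, in which only Col-0 summits of the same number were removed, there were 3504 sites, 3839 target genes and 12 called lists. Leaving out an ARR12-GFP library gives no overlap between replicates, so that value has no such alternative. The motif and 6-mer alternatives were not run.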

Other observations

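The tests of families, hypoxia genes, gene length, space outside genes, housekeeping genes and pseudogenes were chosen only after the results they address were seen. Genes grouped by the stem of their symbol, 205 families with at least 8 members, were compared with all other genes, and 5 families held more targets at an adjusted p under 0.05 in Fisher's exact test, two-sided here throughout. Arabinogalactan proteins (AGP), glycoproteins of the cell surface, had 14 targets of 30 (46.7%; Fisher's exact test, adjusted p = 0.00222), with sites inside AGP9, AGP15 and AGP16. WRKY transcription factors had 23 of 67 (34.3%; Fisher's exact test, adjusted p = 0.00222), led by WRKY22 at 1090 bp with scores of 83.9 and 60.1. ACR genes had 7 of 11 (63.6%; Fisher's exact test, adjusted p = 0.0140), with sites inside ACR8 and ACR4 (AT1G69040). JAZ repressors of jasmonate signalling had 6 of 10 (60%; Fisher's exact test, adjusted p = 0.0484), led by JAZ3 at 74 bp with scores of 75.9 and 62.4, and CIPK protein kinases had 9 of 21 (42.9%; Fisher's exact test, adjusted p = 0.0497). Neighbouring family members can share a site, so members are not independent.

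LBD41 and AT3G10040 (HRA1), both known low-oxygen response genes, stood among the 10 highest-scoring sites, which led to a list of 16 hypoxia genes. Of these 8 were targets (50%; Fisher's exact test, p = 0.000654), including PCO1, PCO2, PDC2 and ADH1, against 14.0% of other genes. The ADH1 site scored 6.34 and 6.47, at percentiles 24.1 and 39.2 of replicates 1 and 2, and the same site made PIN6 a target. HRE2 counted through a site at percentiles 43.0 and 5.79. Without the pair that prompted the list, 6 of 14 were targets (42.9%; Fisher's exact test, p = 0.00816). That ARR12-GFP sites are frequent at hypoxia genes is a hypothesis found and tested on the same data, and the housekeeping list also exceeded other genes. The sites with the highest 10% of mean score percentiles lay over 1500 bp from any protein-coding gene more often than the others, 85 of 351 (24.2%) against 425 of 3152 (13.5%; Fisher's exact test, two-sided, p = 3.85e-07).

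Summits found in ARR12-GFP replicate 2 with no replicate 1 summit within 1000 bp lay inside protein-coding genes in 438 of 788 cases (55.6%), against 999 of 3375 (29.6%) of the corresponding replicate 1 summits (Fisher's exact test, p = 1.97e-41). The share is near the 54.2% of uniform placement. Chance calls spread evenly over the whole genome are argued against, since 4.44% (interval 3.11 to 6.12) lay in the 20% of 100 kb bins poorest in genes. Col-0 summits were called in those bins, but how well reads map there is unknown. The corresponding replicate 1 summits had a similar 5.16% there. Chance calls limited to sequence where reads map therefore stay open. Weak summits as the whole cause are also argued against, as 48.9% (41.4 to 56.4) of the 180 at or above the list's median score were inside genes. The interval cleared the limit set beforehand only narrowly, and the share lay below the 55.6% of all 788. The median score of the 788 was 5.63, against 8.69 for replicate 2 summits matched within 200 bp. A part played by weak scores therefore stays open. Strong transcription may contribute and stays open: 0 of 48 ribosomal protein genes had such a summit, an odds ratio of 0 with an upper limit of 5.32, while 3 of 17 housekeeping genes did (odds ratio 14.3, interval 2.63 to 51.6, against 3.61, 0.400 to 15.6, for replicate 1), a check made without a written prediction. No biological explanation was tested, since both libraries are of 1 group.

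The excess of targets in the lists of hormone, root and growth genes could come from properties of the genes. Gene length and space outside genes are argued against as the whole cause over all 15 study lists, called or not: 95 of their 254 genes (37.4%, interval 31.4 to 43.7) were targets, against 15.1% in random draws matched on length and 16.5% in draws matched on that space (one-sided permutation p = 0.0001 for each, the smallest possible). For single lists space stays open, since 10 of the 11 called lists exceeded 95% of lists matched on it before adjustment, and cytokinin metabolism and expansins with proton pumps did not pass after it. Whether active genes in general lie near sites cannot be told apart from an excess of these lists, since 6 of 17 housekeeping genes (35.3%) were targets, which gives the 15 lists an odds ratio of 1.1 (interval 0.357 to 3.73). A role of ARR12 at these genes stays open, and no expression data were used here.

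Sites shared by the Col-0 libraries numbered 146, and 82 of them (56.2%, interval 47.7 to 64.4) lay in the 20% of bins poorest in genes, against 4.11% of reproducible ARR12-GFP sites. Reads piling up at repeated sequence could produce such sites. A share of 12.3% (7.47 to 18.8) lay within 1000 bp of an annotated pseudogene, against 2.28% of reproducible ARR12-GFP sites and 15.6% of uniform placements. The comparison with the ARR12-GFP sites goes with repeats, while that with uniform placements by the rule first written argues against them. That rule was made stricter after the value was seen, because the interval includes uniform placement and unannotated repeats are not covered, so the explanation stays open. No biological explanation was tested.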
